A study of Homo sapiens and Mus musculus with 14 samples.

How the data were processed

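Genome-wide guide libraries from CNC cells and a plasmid pool, and total and polysome RNA libraries from HL-60 cells with an shRNA against DDX6 or a control shRNA, were compared through 3 tables that the authors deposited. The samples were grouped by their titles, which gave 4 HL-60 groups of 3 libraries and 1 library each for CNC cells and the plasmid pool. The submitters' processing notes name Bowtie2, featureCounts, MAGeCK, FastQC, STAR, SAMtools and DESeq2 with no versions, and the builds GRCh38 and hg38, without saying which step used which. Polysome and total RNA were isolated with TRIzol, and the libraries were built by a sequencing company, per the labels' protocols. Whether those libraries kept strand and how RNA was selected are not given in the sources used here, so reads of overlapping and antisense genes may not be told apart.

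The total RNA table holds, per the file headers, DESeq2's log2 fold changes of shDDX6 over shCTRL with their standard errors, Wald scores, p-values and adjusted p-values as the authors deposited them. Its mean level is a signal value, a mean of normalised counts by the authors. That mean covers more libraries than the 6 compared, since some genes with a fold change of exactly 0 have high means. The table lists 26929 genes, of which 7461 have no fold change and 13178 have an adjusted p. Benjamini-Hochberg adjustment of the deposited p-values gave back the deposited adjusted values. The polysome table gives, per the file headers, the log2 fold changes of total and polysome RNA, the log2 polysome to total RNA ratio in each condition with replicates pooled by the authors, and the log2 change of that ratio in a first, a second and a final version with p-values. The first version equals the polysome minus the total RNA change for 99.8% of the 10333 genes within 0.01, the second equals the difference of the ratios for 99.7%, and the final one takes the version with the larger p, which was the first for 96.5% of genes. The program is not given in the sources used here. Its control columns were read as the shCTRL of the titles. The knockdown ratio carries a number in its name that is not explained, and it was read as the shDDX6 of the titles. Pooling of replicates was inferred from a single value per condition. The screen table gives the authors' log fold change of CNC cells over the plasmid pool per gene, read here as log2 because the base is not given, and a scaled score. That deposited score sets the median of genes marked essential to −1 and that of the others to 0.

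No value per library was used, so no model was refitted, no library was left out and no replicate spread was computed. The planned edgeR and limma fits of the 4 groups needed other units than these tables hold, and the planned fallback, the authors' own comparison, was used. Depth per sample is unknown. The 10th to 90th percentile of the standard errors in total RNA ran from 0.171 to 0.964 on the log2 scale, and 9.49% of tested genes had 1 or more. Genes were called at a deposited adjusted p under 0.05 and never on an adjusted p left empty. Symbols were brought up to date through their Entrez numbers with the RefSeq table of assembly GRCh38.p14, which matched 26787 numbers, left 142 unmatched and renamed 2639 genes.

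Before the data were examined, 28 human and 11 mouse gene lists and the rule for named genes were fixed. The rule names DDX6, then the 12 largest increases and the 12 largest decreases among called genes with a mean level of at least 100, leaving out clone names and pseudogenes. It also names up to 4 called members of each list and the P-body genes, and in the screen the 12 lowest and 12 highest genes. Some genes and 1 list covered by these rules are not reported here. In the polysome and ratio comparisons no gene was called, so members of the lists with high or low values or low p-values were named after their values were seen. Lists with at least 5 measured members were tested with limma 3.58.1 in R 4.3.3 (cameraPR, preset correlation 0.01, Benjamini-Hochberg over lists). The statistic was the Wald score for total RNA and a signed z made from the final p-value for the ratio. A correlation between genes could not be estimated without values per library, so 0.05 was tried as a larger preset. The count over the list alone adjusts the deposited p-values within a list. Polysome list medians were set against 10000 random lists drawn from 20 bins of mean level, and screen medians against 10000 random lists of the same size. For lists past the ratio set test, 10000 random lists of other genes were also drawn in 3 ways. These were from 50 bins of mean level, from 50 bins of genomic span and from 100 joint classes of genomic span and mean level. Shares have Wilson 95% intervals, which cover counting error only. Expected overlaps are products of list sizes over the 10330 genes in both tests. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6 did the remaining steps, with 1000 bootstrap samples for intervals of slopes, medians and rank correlations.

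The methods were tried on simulated data in which genes were independent of each other. For the total RNA set tests over 13178 genes, lists of ribosomal protein and maturation genes shifted by 1 SD were recovered in 100% of 50 draws. A shift of 0.5 SD in G2/M genes was recovered in 40%, and 0.182% of unshifted lists passed. These rates do not cover lists whose genes vary together. For the screen's random lists over 18302 genes, 100% of 100 shifted lists and 2% of unshifted lists lay below the 2.5th percentile. A simulated slope of 1 with error in the total RNA values over 10333 genes came out as 0.763 beside a reliability of 0.756. Alternatives covered thresholds, Holm adjustment, filters on mean level, standard error and gene type, the centre and limit of the screen, the version of the ratio test, and the statistic, ranks and preset correlation of the set tests.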

Results

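By its title the series concerns RNAs held in P-bodies, the cytoplasmic granules of untranslated mRNA and decay factors, in myeloid leukaemia. The 14 samples covered a genome-wide CRISPR knockout screen and RNA sequencing after knockdown of DDX6, an RNA helicase of P-bodies. The screen used CNC cells, a murine leukaemia line labelled as carrying an N and a C mutant form of Cebpa, the gene of a myeloid transcription factor. It had 1 library of guide sequences from the cells and 1 from the plasmid pool. The other 12 libraries came from HL-60, an established human promyelocytic leukaemia line. They fell into 4 groups of 3, namely total RNA and polysome RNA from cells with an shRNA against DDX6 or with a control shRNA. Polysome RNA is the RNA recovered from mRNAs loaded with several ribosomes. The 3 tables used here hold 1 row per gene of the authors' own comparisons and no value per library, so the depth is unknown and the authors' standard errors carry the precision. The labels do not say whether the 3 replicates were separate cultures, so the spread behind the p-values may be technical. The authors' mean levels in total RNA cover more libraries than those compared. The standard errors and p-values there may therefore also carry the spread of those further libraries, which were not analysed here.

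The screen asked which genes CNC cells need for growth. Guides against Ddx6 were strongly depleted, with a log fold change of −2.66 in the authors' deposited table, which put the gene at rank 322 of 18302. Depletion was as deep for Edc4 (−2.66), a scaffold of the decapping complex, and nearly so for Dcp1a (−2.31), an activator of decapping, in the authors' deposited table. The 454 genes that the authors' deposited table marks as essential had a median of −2.27 and all lay below 0, and the other genes had a median of 0.03. On the scale that sets the essential median to −1 and the median of the others to 0, 703 genes lay at or below −1 and are called depleted here. They included 227 of the genes marked essential, a number fixed by the limit, which is the median of those genes. On the other side 10 genes lay at or above 1 and are called enriched. With 1 library per group the screen had no replicate check, so no gene was tested, and the base of the logarithm and the number of guides per gene were not given.

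The lowest genes of the screen belonged to several processes. Sympk, a scaffold of mRNA 3′ end processing, stood lowest at −4.74 in the authors' deposited table. Timm10 (−4.40), Cyc1 (−4.35), Iba57 (−4.05) and Uqcrq (−3.99), all mitochondrial, followed in the authors' deposited table. The ribosomal protein genes Rpl23a and Rpl27a had −4.32 and −4.13, and Rpf2, a ribosome assembly factor, had −3.84, as listed in the authors' deposited table. Gpx4 (−4.31), which guards membranes against lipid peroxidation, Grb2 (−4.16), an adaptor upstream of RAS, Ssrp1 (−3.89), a histone chaperone, and Dmap1 (−3.84) completed the 12 lowest genes of the authors' deposited table. At the other end Hif1a (5.19) and Arnt (3.52), the subunits of hypoxia-inducible factor, stood among the 12 highest of the authors' deposited table. The authors' deposited table also placed there Pecam1 (4.11), Cul5 (3.21) and Ube2f (2.91), the last 2 serving a cullin ubiquitin ligase, and E2f8 (2.91). The haematopoietic transcription factor Ikzf1 had 2.76, the acetyltransferase Kat6a 2.69, the phosphatase Ptprc 2.58, Cux1 2.32 and Chd1 2.25 in the authors' deposited table.

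Among gene lists fixed beforehand, the mRNA decay machinery lay low as a group. The 21 P-body and decapping genes had a median of −0.59, at percentile 0.23 of 10000 random lists of the same size, and 16 of them lay below 0. Ddx6, Edc4 and Dcp1a were the 3 depleted members. Xrn1, the 5′ to 3′ exonuclease, had −1.75, the decapping enzyme Dcp2 −1.45 and Upf1 −1.42 in the authors' deposited table. The P-body genes Lsm14a (0.06), Lsm14b (0.05) and Eif4enif1 (0.39) lay near or above 0 in the authors' deposited table. Other members were Pum2 (−1.19), Cpeb1 (−1.13), Lsm1 (−0.83), Edc3 (−0.74), Zfp36 (−0.59), Patl1 (−0.52), Dcp1b (−0.23), Pnrc1 (−0.16), Igf2bp1 (−0.02), Mex3a (0.68) and Ythdf2 (0.89) in the authors' deposited table. The 15 genes of the CCR4-NOT and PAN2-PAN3 deadenylases had a median of −1.42, below all random lists, and Cnot3 (−2.81) and Cnot2 (−2.29) were depleted in the authors' deposited table. The 13 genes of microRNA silencing had a median of −1.06 (percentile 0.12), with Dicer1 at −2.49 as the only depleted member in the authors' deposited table. For the 12 stress granule genes the median was −0.47 (percentile 3.04), and Caprin1 at −2.42 was depleted in the authors' deposited table. The random lists, here and for the lists that follow, came from all 18302 genes and were not matched on expression. A low percentile therefore does not set a list apart from other expressed genes.

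Housekeeping lists marked the lower end of the scale. Medians were −2.51 for 72 ribosomal protein genes (48 depleted), −2.21 for 31 proteasome genes (14 depleted), −2.23 for 25 spliceosome genes (12 depleted) and −2.39 for 10 RNA polymerase II genes (6 depleted), each below all random lists. Of these genes 62, 20, 18 and 7 in turn are marked essential, so they helped to set the limit for depletion. The lowest members of the proteasome, spliceosome and RNA polymerase II lists were Psmd13 (−3.09), Prpf19 (−3.29) and Polr2d (−3.20) in the authors' deposited table. Transcription, chromatin and signalling genes that myeloid leukaemias depend on formed a list of 39 with a median of −1.61, also below all random lists. Of its 6 depleted members, Myb (−3.18), Spi1 (−2.70), Jak2 (−2.67) and Ythdc1 (−2.55) were the lowest in the authors' deposited table, while Dot1l lay at 1.67. The 34 tumour suppressors had a median of 0.04 (percentile 58.1), and Nf1 (2.04) and Cdkn2a (1.58) were among the highest in the authors' deposited table. No gene was named as an olfactory receptor, the list planned as unexpressed background. In its place, 292 chemosensory receptor genes chosen after the data were seen had a median of −0.07, and their central 95% ran from −1.72 to 0.78, with 2 depleted and 0 enriched.

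**Figure D1:**
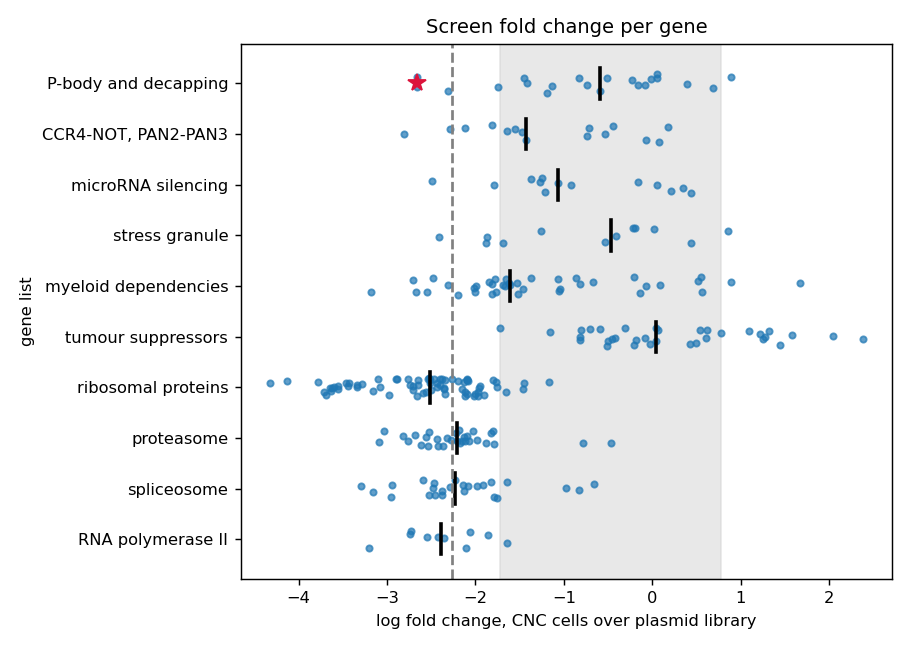
Log fold change of CNC cells over the plasmid library for the genes of 10 lists, 1 point per gene, with list medians as black bars and Ddx6 as a star. The dashed line is the median of the genes marked essential (−2.27) and the grey band holds the central 95% of the chemosensory receptor genes (−1.72 to 0.78); the P-body and decapping list has a median of −0.59 and Ddx6 lies at −2.66.

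The total RNA comparison asked what the knockdown of DDX6 does to mRNA levels in HL-60 cells. DDX6 itself (chromosome 11, positions 118747763 to 118791744, GRCh38.p14) fell to 0.445 of its control level, a log2 fold change of −1.17 ± 0.24 (SE) with a DESeq2 adjusted p of 4.2e-05 in the authors' deposited table. At an adjusted p under 0.05, 1252 genes rose and 721 fell, together 15% of the 13178 genes with an adjusted p, and 1892 of those called were protein coding. The typical called change was moderate, with medians of 0.86 for genes that rose and −0.86 for genes that fell, and 475 and 288 of them changed at least 2-fold. Monocyte and granulocyte genes, ribosomal protein genes and respiratory chain genes rose as groups, and zinc finger genes fell as a group. The set tests behind these calls were not matched on mean level or genomic span, with which total RNA changes also varied. At a preset correlation of 0.05 between genes the calls for maturation genes (adjusted p = 0.14) and zinc finger genes (adjusted p = 0.203) were lost, and the respiratory chain call was lost with the log2 fold change as statistic (adjusted p = 0.141). Of the tested genes, 394 had a log2 fold change of exactly 0, 6 of them in the histone list, 6 in the zinc finger list and 2 in the self-renewal list, and leaving them out kept 8 lists past the set test. The median standard error was 0.288 on the log2 scale, and 84 of the called genes had a standard error of at least 1.

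The 12 largest increases lay between 3.41 and 6.91 on the log2 scale in the authors' deposited table. ASGR2, a subunit of the hepatic asialoglycoprotein receptor, rose by 4.33 ± 0.71 (SE), DACT3, an antagonist of Wnt signalling, by 4.0 ± 0.79, TP53I11 by 3.69 ± 0.73 and SUSD3 by 3.41 ± 0.78 on the log2 scale in the authors' deposited table. Wider errors came with CUX2, a homeobox gene (6.91 ± 1.30), CD180, a Toll-like receptor homologue (6.47 ± 1.31), DEPP1 (listed as C10orf10, 4.60 ± 1.27) and POLR1H (listed as ZNRD1, 4.47 ± 1.27) in the authors' deposited table. MYO15B (4.37 ± 1.42), DNAJC15 (4.15 ± 1.29), PTGFRN (3.75 ± 1.34) and KRT18 (3.65 ± 1.19) completed the 12 largest increases in the authors' deposited table. Among the decreases, RAP2A, a small GTPase, had −4.61 ± 0.72, ARMCX5 −3.98 ± 0.70, NRGN, a calmodulin-binding protein, −3.51 ± 0.80 and PRELID3A −3.33 ± 0.86 in the authors' deposited table. TP73 (−5.0 ± 1.24), GAREM2 (−4.42 ± 1.27), LPL, lipoprotein lipase (−4.27 ± 1.38), and SYNPO2 (−3.98 ± 1.28) fell with wider errors in the authors' deposited table. LAMP5 (−3.86 ± 1.27), MS4A6A (−3.83 ± 1.31), FEZ1 (−3.70 ± 1.06) and GALC (−3.53 ± 1.29) completed that group of 12 in the authors' deposited table. The mean level behind the rule for these names was computed over more libraries than the 6 compared, so it is not a level in HL-60.

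**Figure D2:**
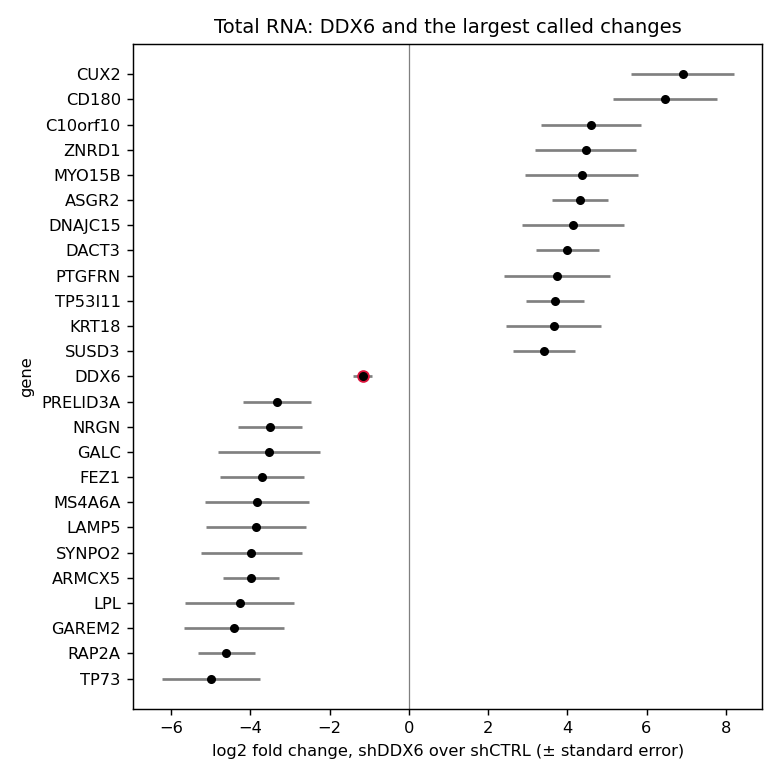
Log2 fold change in total RNA, shDDX6 over shCTRL, for DDX6 (red point) and the 12 largest increases and decreases among called genes with a mean level of at least 100. Points are the authors' estimates and lines are ± 1 standard error. DDX6 has −1.17 ± 0.24, and 16 of the other 24 genes have a standard error of at least 1.

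Genes of monocyte and granulocyte maturation rose as a group. Of 40 tested, 9 rose and 1 fell, with 10 and 1 adjusted over the list alone, and the list median was 0.57 with 29 members above 0. IRF8, a transcription factor of the monocyte lineage, rose by 2.91 ± 0.44 (SE), CD68, a lysosomal protein of macrophages, by 2.04 ± 0.37, and the receptor of colony stimulating factor CSF1R by 1.41 ± 0.49 in the authors' deposited table. NCF1, a subunit of the phagocyte oxidase, had 2.29 ± 0.45 in the authors' deposited table, a value that is uncertain because near-identical gene copies exist and reads shared with them were not tested. KLF4 (1.34), CYBB (1.19), ITGB2 (1.14), FCGR2A (0.86) and CEBPD (0.85) rose as well, while CXCR2 fell with −0.53 in the authors' deposited table. The list moved upward against all other genes (limma cameraPR, preset correlation 0.01, Benjamini-Hochberg adjusted p = 0.00305), a call lost at a preset correlation of 0.05 (adjusted p = 0.14). Markers of other cell types stood beside this group as follows. None of 10 lymphoid markers was called (0 adjusted over the list alone, adjusted set p = 0.797), with CD4 at 0.60 ± 0.36 and NKG7 at 0.81 ± 0.36 in the authors' deposited table. Of 6 fibroblast, epithelial and endothelial markers, the keratins KRT18 and KRT8 (1.51 ± 0.51) rose in the authors' deposited table, also over the list alone, and the set did not pass (adjusted p = 0.549). Of 2 erythroid markers tested, EPOR rose with 0.86 ± 0.29 in the authors' deposited table, the same call as over the list alone, and too few were measured for a set test. The lymphoid list median was 0.42 and that of the fibroblast, epithelial and endothelial list 0.28, beside 0.57 for maturation genes. Median standard errors were 0.68, 0.75 and 0.42 in turn. These short lists with wider errors therefore do not show the rise to be particular to maturation genes.

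Genes of the promyelocyte primary granules and of leukaemic self-renewal moved in both directions. Of 13 granule and precursor genes 3 rose and 1 fell, with 3 and 2 adjusted over the list alone. The neutrophil proteases CTSG and ELANE rose by 1.60 ± 0.37 and 1.58 ± 0.59 and the granule proteoglycan SRGN by 0.71 ± 0.20, whereas IGLL1 had −1.89 ± 0.47 in the authors' deposited table. Of 20 self-renewal and progenitor genes, 2 of them with a log2 fold change of exactly 0, MEF2C (1.78) and CD44 (1.04) rose and the receptor tyrosine kinase FLT3 (−1.74) and the homeobox gene PBX3 (−0.89) fell in the authors' deposited table, with 2 and 2 adjusted over the list alone. Of 45 chromatin regulators and other tumour suppressors of myeloid neoplasms 4 rose and 1 fell, the same numbers as over the list alone. Among them TSC2 (0.91), SH2B3 (0.68) and DNMT3A (0.62) rose and RUNX1 (−0.59) fell in the authors' deposited table. None of these lists passed the set test (adjusted p = 0.797, 0.829 and 0.549, limma cameraPR).

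P-body genes moved in both directions. Of 21 tested, 3 rose and 4 fell, with 3 and 5 adjusted over the list alone, and the set did not pass (adjusted p = 0.699, limma cameraPR). PNRC1, an activator of decapping, rose by 1.17 ± 0.21, ZFP36, which binds AU-rich mRNAs, by 0.71 ± 0.25 and the transporter EIF4ENIF1 by 0.39 ± 0.13 in the authors' deposited table. MEX3A (−1.35 ± 0.34) and YTHDF2 (−0.48 ± 0.17) fell beside DDX6 in the authors' deposited table. Not called there were NBDY (listed as LINC01420, −0.62), EDC4 (0.44), DCP1A (−0.33), PATL1 (0.33), PUM2 (−0.31), DCP2 (−0.31), XRN1 (−0.29), LSM14A (0.24), IGF2BP1 (0.22), LSM14B (0.12), UPF1 (−0.11), EDC3 (0.11), DCP1B (−0.08) and LSM1 (−0.06), all from the authors' deposited table. Of 15 deadenylase genes CNOT4 fell with −0.75 ± 0.19, and of 13 microRNA silencing genes the Argonaute gene AGO2 rose by 0.73 ± 0.24 in the authors' deposited table. Each was also the single call over its list alone, and neither list passed the set test (adjusted p = 0.518 and 0.797).

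Ribosomal protein and oxidative phosphorylation genes shifted upward. Of 78 ribosomal protein genes 12 rose and 0 fell, 25 and 0 adjusted over the list alone, 77 lay above 0 and the median was 0.62. RPL37 rose by 1.26 ± 0.34, RPS14 by 1.09 ± 0.34 and RPS23 by 1.07 ± 0.30 in the authors' deposited table. RPS18, at 2.98 ± 1.06 in the authors' deposited table, is uncertain because its mean level was only 5.14, and reads shared with its processed copies were not tested. Of 54 nuclear-encoded oxidative phosphorylation genes 10 rose and 0 fell, 13 and 0 over the list alone, with a median of 0.32. UQCRQ rose by 1.18 ± 0.24, NDUFS3 by 0.96 ± 0.19, NDUFA2 by 0.86 ± 0.20 and COX7C by 0.83 ± 0.21 in the authors' deposited table. Both lists passed the set test (limma cameraPR, adjusted p = 2.17e-09 and 1.60e-05) and kept the call at a preset correlation of 0.05 (adjusted p = 0.00221 and 0.0217). For oxidative phosphorylation the call was lost with the log2 fold change in place of the test statistic (adjusted p = 0.141). Total RNA changes also varied with mean level and genomic span. Other genes nearest in mean level to the ribosomal protein genes had a median of 0.38. Medians were 0.20 in the 2064 genes of shortest span and −0.14 in the 2064 of longest span. The set tests of total RNA, for these and the other lists, were not matched on level or span. How far such trends shifted a list therefore stays open. Of 42 translation factors 7 rose and 0 fell, the same over the list alone, led by EIF3F (0.93 ± 0.27), EEF2 (0.92 ± 0.26), EEF1A1 (0.76 ± 0.28) and EIF3K (0.74 ± 0.23) in the authors' deposited table, and the set did not pass (adjusted p = 0.549). Nucleolar genes of ribosome biogenesis went the other way, with 1 risen and 4 fallen of 38, the same over the list alone, a median of −0.19 and an adjusted set p of 0.0436. NHP2 rose by 0.84 ± 0.24, and DDX10 (−0.82 ± 0.27), RRS1 (−0.55 ± 0.18) and GNL3 (−0.54 ± 0.20) fell in the authors' deposited table. That set lost its call at a preset correlation of 0.05 (adjusted p = 0.273). The 13 mitochondrially encoded mRNAs were not analysed here.

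Genes of cholesterol synthesis and glycolysis rose in part. Of 23 cholesterol genes 7 rose and 1 fell, 8 and 1 over the list alone, with a median of 0.35 and an adjusted set p of 0.0134 (0.14 as the adjusted p at a preset correlation of 0.05). Lanosterol synthase LSS rose by 1.23 ± 0.36, FDFT1 by 0.90 ± 0.25 and MVK by 0.88 ± 0.21, and CYP51A1 fell with −0.54 ± 0.20 in the authors' deposited table. Of 22 glycolysis genes 7 rose and 1 fell, 10 and 2 over the list alone, with a median of 0.34 and an adjusted set p of 0.0436 (0.249 as the adjusted p at a preset correlation of 0.05). PFKFB4, a regulator of glycolytic flux, rose by 1.80 ± 0.31, the glucose transporter gene SLC2A3 by 1.77 ± 0.54 and the hexokinase gene HK1 by 1.14 ± 0.36, and the phosphofructokinase gene PFKM fell with −1.79 ± 0.41 in the authors' deposited table. Zinc finger genes named ZNF formed the largest list that fell, with 10 risen and 35 fallen of 411, 8 and 29 over the list alone, and a median of −0.26. ZNF717 (−3.02 ± 0.76), ZNF829 (−3.08 ± 0.71), ZNF154 (−3.14 ± 1.16) and ZNF396 (−3.30 ± 1.14) had the largest decreases among called genes of the list in the authors' deposited table. Its adjusted set p was 0.000205, or 0.203 as the adjusted p at a preset correlation of 0.05. Replication-dependent histone genes, whose mRNAs lack a poly(A) tail and so depend on how the RNA was selected, rose in 4 of 44 cases and fell in 0, also over the list alone. H3C11 (3.54 ± 1.17), H4C3 (2.0 ± 0.67), H1-4 (1.80 ± 0.59) and H1-2 (1.18 ± 0.33) were those in the authors' deposited table. The list median was 0.72 and the adjusted set p 0.0380 (0.273 as the adjusted p at a preset correlation of 0.05), and this shift stood beside the upward lists above. Only 3 of the 44 had a mean level of at least 100, and the median standard error was 0.69. Among histone genes with a standard error under 1 the set lost its call.

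Stress, growth and cell death lists did not pass the set test. Of 20 apoptosis genes BBC3 (1.22), BAK1 (1.12) and BAD (0.76) rose and the death receptor gene FAS (−1.03) and PMAIP1 (−0.87) fell in the authors' deposited table, 3 and 3 over the list alone (adjusted set p = 0.946). Of 40 S phase genes GINS4 (0.37) rose and MCM6 (−0.70), RRM1 (−0.70) and RFC3 (−0.60) fell in the authors' deposited table, 0 and 2 over the list alone (0.717). Of 40 G2/M genes 5 rose and 3 fell, the same over the list alone (0.829), among them CDC25C (1.09), KIF20A (0.93) and CDK1 (−0.83) in the authors' deposited table. Of 37 interferon-stimulated genes XAF1 (2.17) and IFITM2 (0.69) rose in the authors' deposited table, also over the list alone (0.797). Of 28 ATF4 targets ALDH1L2 (−2.40), the cystine transporter gene SLC7A11 (−1.18) and CEBPG (−0.50) fell in the authors' deposited table, 1 over the list alone (0.374). Of 20 genes of the unfolded protein response the chaperones HSP90B1 (−0.78) and PDIA3 (−0.45) fell in the authors' deposited table, 0 over the list alone (0.549). Of 18 inflammatory mediators IL1RN (1.55), TNFAIP2 (1.17) and SOD2 (0.63) rose in the authors' deposited table, with 3 risen and 1 fallen over the list alone (0.829). Of 23 immediate early genes KLF2 (1.19), JUN (0.84) and ZFP36 rose and FOSL1 (−1.39) and MCL1 (−0.44) fell in the authors' deposited table, 4 and 2 over the list alone (0.946).

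The polysome comparison asked how the knockdown changes the RNA loaded on ribosomes. DDX6 RNA on polysomes had a log2 fold change of −1.23 in the authors' deposited table, close to its change in total RNA. Among the 10333 genes of that table, 261 had a polysome change of at least 1 and 238 of at most −1, against 423 and 289 for total RNA in the same genes. The table gives no error or p-value for the polysome change, so no gene is called and the values are descriptive. Of the genes that rose in total RNA, 1145 had a polysome value, and 1071 of these (93.5%, Wilson 95% interval 92.0% to 94.8%) also lay above 0 on polysomes. Of the 654 that fell in total RNA, 633 (96.8%, 95.1% to 97.9%) lay below 0 on polysomes. Medians were 0.40 on polysomes against 0.81 in total RNA for genes that rose, and −0.41 against −0.83 for genes that fell, a gap that picking the genes by their total RNA call widens by itself. Across genes, which are not independent replicates, total and polysome changes had a Pearson correlation of 0.690 and a Spearman correlation of 0.463. CD180 (4.65) and ASGR2 (3.17) were high on polysomes, and ARMCX5 (−3.88), LPL (−3.86) and RAP2A (−3.37) were low, in the authors' deposited table.

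The gene lists on polysomes were set against 10000 random lists matched on mean level but not on genomic span. Polysome changes rose with span. Their median was −0.15 in the 2064 genes of shortest span and 0.12 in the 2064 of longest span. A list of short or long genes may therefore lie low or high through this trend. Maturation genes stood highest, with a median of 0.35 (percentile 100) and IRF8 at 2.30, NCF1 at 1.77, CYBB at 1.73 and CD68 at 1.61 in the authors' deposited table. Myeloid tumour suppressors had a median of 0.30 (percentile 100), with ASXL2 (0.77) and SH2B3 (0.75) highest in the authors' deposited table. Cholesterol genes had 0.26 (percentile 99.9), interferon-stimulated genes 0.23 (98.2), microRNA silencing genes 0.22 (96.4) and G2/M genes 0.21 (percentile 100 after rounding). Granule and precursor genes had −0.40 (percentile 0), although CTSG (1.33) and SRGN (0.88) were high in the authors' deposited table, and the low members there included IGLL1 (−2.52) and RNASE2 (−0.93). Ribosomal protein genes had −0.28 (percentile 0), ATF4 targets −0.23 (0.06), inflammatory mediators −0.27 (0.79), ribosome biogenesis genes −0.13 (2.5) and immediate early genes −0.18 (2.91). Between these lay zinc finger genes with −0.05 (3.82), oxidative phosphorylation genes with −0.08 (12.9), P-body genes with −0.06 (22.4) and S phase genes with −0.04 (29.1). Glycolysis genes had −0.01 (59.1), unfolded protein response genes 0.00 (60.0), self-renewal genes 0.06 (75.7), histone genes 0.20 (86.4), translation factors 0.02 (87.3), deadenylase genes 0.12 (89.9) and apoptosis genes 0.12 (90.9).

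**Figure D3:**
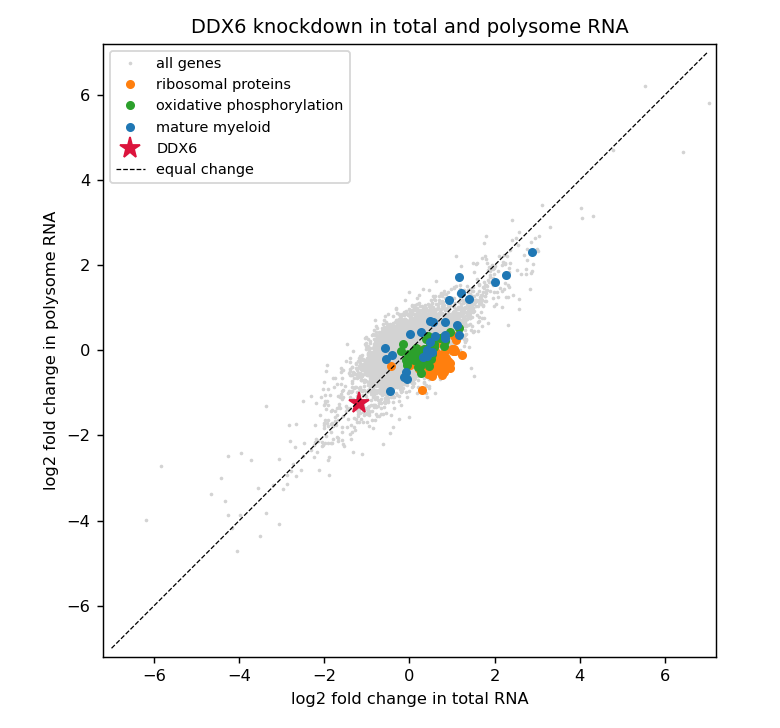
Log2 fold change in polysome RNA against that in total RNA, shDDX6 over control shRNA, 1 point per gene for 10333 genes, with ribosomal protein, oxidative phosphorylation and mature myeloid genes in colour, DDX6 as a star and the line of equal change dashed. Ribosomal protein genes lie right of and below the line (medians 0.60 in total RNA and −0.28 on polysomes), and DDX6 lies close to it (−1.23 on polysomes, ratio change −0.05).

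The change of the polysome to total RNA ratio, also called translational efficiency, asked whether ribosome loading per mRNA changed. Ribosomal protein and oxidative phosphorylation mRNAs had a lower ratio as groups. Of 77 ribosomal protein genes 76 had a lower ratio after knockdown, with a median change of −0.84, and the median log2 ratio went from −0.91 in control cells to −1.72. RPL37 (−1.35), RPS28 (−1.32), RPL37A (−1.33) and RPL28 (−1.35) had the lowest p-values of the list in the authors' deposited table. Over the list alone 67 of them passed with a lower ratio and 0 with a higher one, against 0 of either kind over all genes. For oxidative phosphorylation 52 of 54 genes were lower, 4 of them over the list alone, with a median of −0.41 and COX7C (−0.72) and ATP5F1E (−0.82) lowest in p in the authors' deposited table. Most of either median came from total RNA, which had 0.60 for ribosomal protein and 0.30 for oxidative phosphorylation genes, beside −0.28 and −0.08 on polysomes. That −0.08 lay within random lists matched on mean level but not on genomic span (−0.12 to 0.05), and the −0.28 below them. Both sets passed (limma cameraPR on signed z values, adjusted p = 6.55e-35 and 1.06e-08), also at a preset correlation of 0.05 (adjusted p = 4.97e-13 and 0.000848). Short and abundant genes had a lower ratio change in general. Random lists, 10000 of other genes in the same classes of genomic span and mean level, were therefore added after the data were seen. Their central 95% ran from −0.45 to −0.29 for oxidative phosphorylation, which holds its median of −0.41 (percentile 25.4), and from −0.49 to −0.40 for ribosomal protein genes, whose −0.84 lay below all of them. For DDX6 the ratio change was −0.05 with an adjusted p of 0.900 in the authors' deposited table.

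No single gene passed an adjusted p of 0.05 for the ratio, where the smallest adjusted p was 0.0670. That count rests on the authors' final p, the larger of 2 versions, and with their second version 2365 genes passed (987 higher, 1378 lower). At an unadjusted p under 0.05, 470 genes were higher and 1102 lower in the authors' deposited table, against 517 expected by chance for both together. The program behind these p-values is not stated. Below 0.1 lay 5 genes, the ribosomal protein genes RPL37, RPS28, RPL37A and RPL28 and the peptidyl-tRNA hydrolase gene PTRHD1 (−1.21), chosen after their values were seen in the authors' deposited table. With the final p, the overlap of genes called for both total RNA and the ratio was therefore 0. Of the genes that rose in total RNA, 343 had a lower and 1 a higher ratio at an unadjusted p under 0.05, where independent lists would share 122 and 52.1. Of those that fell, 105 had a higher and 2 a lower ratio, against 29.8 and 69.8. Total RNA enters both measures, which alone makes them move oppositely. Their covariance across genes was −0.163, beside −0.0874 computed from the error of the total RNA values alone.

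Other lists moved less in the ratio. Zinc finger genes were higher, 216 of 340, with a median of 0.23 and an adjusted set p of 0.00102 (0.275 as the adjusted p at a preset correlation of 0.05), and ZNF678 (1.61), ZNF432 (1.52) and ZNF92 (1.23) had the lowest p-values in the authors' deposited table. G2/M genes were higher in 25 of 40 cases, with a median of 0.39 and an adjusted set p of 0.0233 (0.275 as the adjusted p at a preset correlation of 0.05). ASPM (1.0), NUF2 (0.94) and NDC80 (0.82), which act at the spindle and kinetochore, were high and UBE2C (−0.71) was low in the authors' deposited table. Glycolysis genes were lower in 17 of 21 cases, with a median of −0.38 and an adjusted set p of 0.0301 (0.273 as the adjusted p at a preset correlation of 0.05), and GAPDH had −0.84 in the authors' deposited table. The glycolysis median lay within random lists matched on mean level (−0.45 to 0.01, percentile 18.3). It lay at percentile 0.47 of those matched on span alone and at 2.62 of those matched on span and level. The list's median changes were 0.36 in total RNA and −0.01 on polysomes. Random lists matched on span and level ran from −0.15 to −0.01 for zinc finger and from −0.30 to 0.09 for G2/M genes, and both medians lay above all of them (percentile 100). In each of these 3 lists 0 genes passed over the list alone. Myeloid tumour suppressors did not pass (adjusted p = 0.0819), with the cohesin genes SMC3 (1.17) and STAG2 (1.08) highest in the authors' deposited table. The other lists did not pass, with an adjusted p of 0.163 for deadenylases (median 0.36), 0.307 for maturation genes (−0.41), 0.394 for self-renewal (0.30), 0.472 for granule genes (−0.25) and 0.559 for immediate early genes (−0.24). For ATF4 targets it was 0.617 (−0.22), for microRNA silencing 0.617 (0.20), for ribosome biogenesis 0.673 (0.05), for apoptosis 0.698 (0.12) and for inflammatory mediators 0.698 (−0.15). For the unfolded protein response it was 0.724 (−0.01), for translation factors 0.762 (−0.03), for cholesterol synthesis 0.762 (−0.28), for P-body genes 0.774 (−0.07), for S phase 0.774 (−0.02), for histones 0.811 (−0.07) and for interferon-stimulated genes 0.832 (0.03). In those lists 0 genes passed over the list alone, except 1 translation factor with a lower ratio, EIF3G (−0.91 in the authors' deposited table). Among markers of other cell types CD79A (−1.09) and EPOR (−0.76) passed over their lists alone with a lower ratio in the authors' deposited table, and KRT8 had −1.06, not passing. The lymphoid list held 3 measured genes and the erythroid list 1, so for EPOR the adjustment changed nothing.

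**Figure D4:**
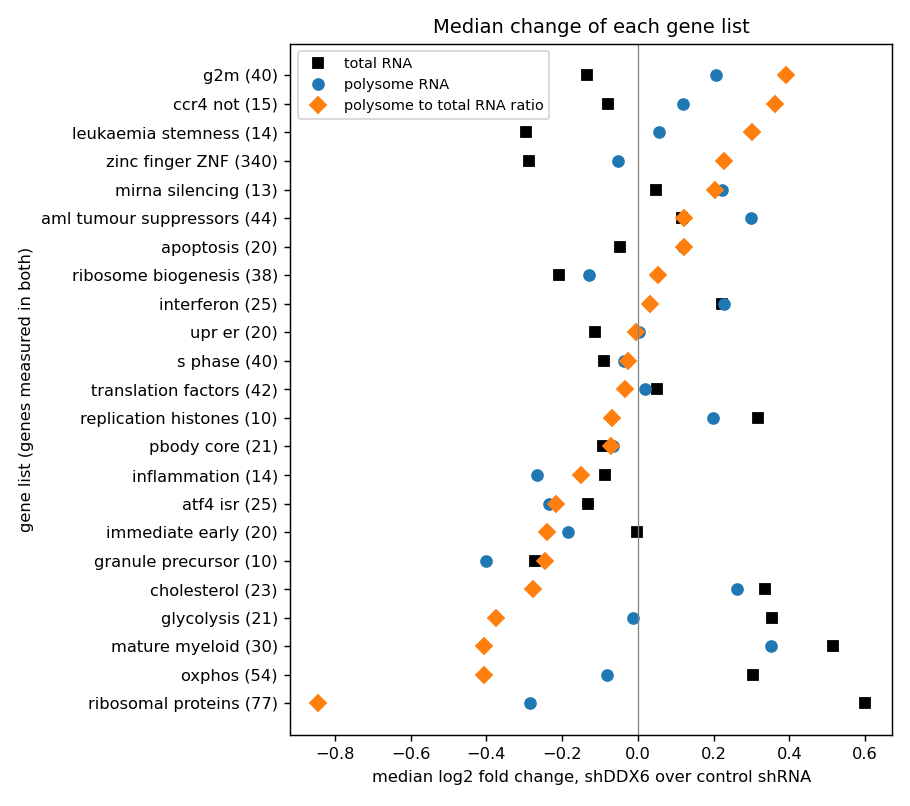
Median log2 fold change, shDDX6 over control shRNA, of gene lists with at least 5 measured members in total RNA (squares), polysome RNA (circles) and their ratio (diamonds), with the number of genes in brackets. Ribosomal protein genes have the lowest median ratio change (−0.84) with a median of 0.60 in total RNA and −0.28 on polysomes, and G2/M genes the highest (0.39).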

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

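Among the tests in this part, those on shared error, abundance and short genes for the ribosomal protein genes, the test of polysome changes against gene span and the bound for the slope without the span trend were chosen only after the result was seen. For total RNA, 98 genes had a log2 fold change of exactly 0, a p-value of 1 and a mean level of at least 100, the level being a signal that the 6 compared libraries do not show. MT1E had the highest mean level among them, 1801, followed by IGF2BP2 with 1359 and ENPP2 with 1240, and MEIS1 (482) and HOXA11 (659) were also there in the authors' deposited table. A mean taken over more libraries than the 6 compared gives such values by construction, and those further libraries were not analysed here.

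Polysome changes were smaller than total RNA changes. The slope of polysome on total RNA change over 10333 genes was 0.576 (95% bootstrap interval 0.552 to 0.597), below the reliability of 0.772 that error in the total RNA values alone would leave. Low precision is argued against by the 2584 genes with the smallest standard errors, whose slope was 0.456 (0.434 to 0.478), below the reliability of 0.801 in those genes. A trend with genomic span in either kind of library left a slope of 0.615 (0.596 to 0.637) after its removal, below the reliability of 0.766 that the total RNA values then had. Normalisation of the libraries one by one, transcript length and GC content were not tested and stay open, so a buffering of mRNA changes at the ribosome may be proposed only as a hypothesis.

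Ribosomal protein genes had a lower polysome to total RNA ratio. Error shared through the total RNA values is argued against by polysome RNA alone, where their median change of −0.28 lay below the range of −0.12 to 0.01 for random lists matched on mean level. Other abundant mRNAs shifted less, since genes nearest in mean level had a median ratio change of −0.36 (−0.41 to −0.26) against −0.84, which argues against abundance as the whole cause, though with an imperfect match (median levels of 32941 and 68788). Between levels of 30000 and 60000, 22 ribosomal protein genes had a median of −0.80 and 23 other genes −0.25, and above 100000 the medians were −0.83 for 18 and −0.49 for 14. Genes nearest in genomic span had −0.37 (−0.43 to −0.27), which argues against short span as the whole cause in the same way, but a part of the shift through level and span, transcript length and GC content stay open, so a loss of ribosomes from these mRNAs may be one of several explanations.

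The ratio change rose with the genomic span of the gene, from a median of −0.36 in the 2064 genes of shortest span (median 5.21 kb) to 0.29 in the 2064 of longest span (138 kb), with a Spearman correlation of 0.432 across genes. Error of the total RNA values is argued against as the whole cause by polysome RNA alone. The polysome change had a correlation of 0.239 (0.220 to 0.259) with span, against −0.208 for total RNA. Without the ribosomal protein and oxidative phosphorylation genes, 10187 of 10318 genes were left and the correlation was 0.420 (0.403 to 0.438). These 2 lists are too small a share of the genes to move it much, so that outcome was nearly fixed beforehand. In control cells the ratio itself fell with span (−0.425) and after knockdown hardly so (−0.068). Transcript length, GC content and a length bias that differs between libraries were not tested and stay open, so a technical cause may account for this trend as well as a biological one.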

How the results depend on the processing

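Filters on the standard error, on gene type and on fold changes of exactly 0, the second and first versions of the ratio test, and the limit and centres of the screen were chosen only after the data were seen. No paired analysis was possible because the tables hold no values per library, and for the same reason the fits with other size factors, DESeq2 in place of edgeR, no filter, all 4 groups, other pseudocounts, a replicate block, left-out replicates and other splits of the samples were not run. FDR thresholds, a minimum of guides, score ranks and a centre on olfactory receptor genes were not run for the screen either, and thresholds on p not for polysome RNA. The 1973 genes called in total RNA became 312 with Holm adjustment, 1047 at an adjusted p of 0.01 and 763 with an absolute log2 fold change of at least 1, and lay between 1796 and 2830 under the other alternatives. The 499 genes with a 2-fold polysome change became 318 at a mean level of at least 100. For the ratio, 0 genes became 5 at an adjusted p of 0.1 and 2365 (987 higher, 1378 lower) with the second version of the p-values, and stayed 0 under the other alternatives tried; the authors' final version takes the larger p of each pair. The screen's 713 depleted or enriched genes became 1246 with the limit at the 75th percentile of essential genes. Of 8 lists past the set test in total RNA, 2 remained in number at a preset correlation of 0.05, 4 with the log2 fold change as statistic and 5 at a standard error under 1, and of 5 lists for the ratio 2 at a preset correlation of 0.05. With the log2 fold change as statistic, total RNA lost oxidative phosphorylation (adjusted p = 0.141), cholesterol (0.403), glycolysis (0.411) and ribosome biogenesis (0.526). At a standard error under 1 it lost glycolysis (0.0564), histones (0.0564) and ribosome biogenesis (0.0544), and at a mean level of at least 100 glycolysis (0.0654) and histones, which kept 3 of 44 genes, too few for a test, so that 6 lists passed. For the ratio, G2/M genes lost the call with the second version of the p-values (0.0627), and myeloid tumour suppressors gained it at a preset correlation of 0 (0.0225). The cause was not tested, except that stricter thresholds and filters leave fewer genes by construction. No list past the set test changed direction under the alternatives run. Among lists that did not pass, immediate early, self-renewal, apoptosis and inflammatory genes in total RNA and interferon-stimulated genes in the ratio did under at least 1 of them. Of the named genes called, 164 lost the call with Holm adjustment and 28 kept it. Unknown depth leaves wide errors for low genes, and 84 called genes have a standard error of at least 1.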

Other observations

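The tests on genes that rose and on a mean level of at least 100, and the groups of screen genes, are treated as chosen only after the results were seen. In the screen, several genes near RAS, picked by their values and not tested as a group, lay far from 0. Next to Grb2, the exchange factor Sos1 had −3.03, the phosphatase Ptpn11 −2.93, Shoc2 −2.64 and Nras −2.00 in the authors' deposited table. Of the negative regulators, Nf1 (2.04), Lztr1 (1.22) and Rasa2 (0.77) lay above 0 and Rasa1 (−0.50) below in the authors' deposited table. Genes of cytokine signalling ranged from Jak2 at −2.67, Stat5b at −2.00, Stat5a at −1.53 and Il3ra at −1.47 to Csf2rb at −0.82, Socs1 at −0.60 and Socs3 at 0.43 in the authors' deposited table.

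Genes of oxygen sensing lay in both directions. Hif1a and Arnt were among the 12 highest genes, whereas Vhl, which marks HIF1A for destruction, had −2.67 and its partners Tceb2, Cul2 and Tceb1 −2.18, −2.01 and −0.32 in the authors' deposited table. The hydroxylases Egln1 and Hif1an had −0.16 and −0.67 and Epas1 0.06 in the authors' deposited table. Several members of the CUL5 ubiquitin ligase were high, with Cul5 at 3.21, Ube2f at 2.91, Arih2 at 1.95, Rnf7 at 1.04 and the adaptors Cish and Socs2 at 1.25 and 1.15 in the authors' deposited table. Its shared subunits Tceb2 and Tceb1 and the adaptor Socs1 were not among the high ones. Ikzf2 (1.85), a relative of Ikzf1, was high as well in the authors' deposited table. With 1 library per group, none of these values has a replicate check.

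In HL-60 cells the genes SNX19 (−2.78 ± 0.55), ZIK1 (−3.54 ± 1.47) and CHAC1 (−0.18 ± 1.11) had a fold change and standard error but no p-value in the authors' deposited table, so they were not called. Zinc finger genes measured precisely, 151 with a standard error below the median, had a median log2 fold change of −0.0701 in total RNA. That lay below the range of −0.02 to 0.17 for random lists of such genes, so low precision alone did not carry their decrease. The median over all 411 was lower, at −0.26, so how far low precision enlarged the decrease stays open. The random lists were not matched on mean level or genomic span, with which total RNA changes also varied. A part of the decrease through level or span stays open as well.

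A hypothesis tested here was that RNAs that fell after DDX6 knockdown encode proteins the leukaemia cells need. Matched by symbol between human and mouse, 38 of 601 genes that fell were depleted in the screen (6.32%), against 563 of 8709 genes not called (6.46%). The odds ratio was 0.977 (95% interval 0.676 to 1.37, two-sided Fisher's exact test p = 1), so the data gave no support to it. Among genes that rose, 4.94% were depleted, an odds ratio of 0.751 (Fisher's exact test p = 0.0492, 0.0983 after Benjamini-Hochberg adjustment over 4 tests). With a mean level of at least 100 that odds ratio was 0.673 (Fisher's exact test p = 0.00507, adjusted 0.0203). The lines come from different species, and the screen has no replicate.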
